A study of Homo sapiens with 8 samples.

How the data were processed

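RNA from the human cholangiocarcinoma cell line HuCCT1 was measured on 8 Affymetrix HG-U133_Plus_2 expression arrays, 4 of cells with a control shRNA and 4 of cells with an shRNA against YAP1. Per the labels' protocols, RNA was column-purified, amplified with a NuGEN kit and labelled with biotin. The deposited values are log2 values, 1 per probe set and array. The log base was inferred from their range of 1.72 to 14.9 and is not stated. The background correction, summarisation and normalization that the authors used are not given in the sources used here. The array medians lay between 6.22 and 6.25, under the limit of 0.5 for their range set beforehand, so the values were used with no further normalization. Values carry no detection call, so dim probe sets could only be set apart by their level. On arrays, the number of arrays limits the precision, and no array pair held identical values.

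The table held 54675 probe sets. GEO's platform annotation gave 1 gene symbol to 41097 of them, several to 1801 and none to 11777. By Entrez ID, 41043 of the probe sets with 1 symbol matched the RefSeq gene table of GRCh38.p14, and 0 symbols changed. That table was used for names and for which genes neighbour each other or share a chromosome, since the files name no genome build. Each of 19775 genes was represented by the probe set with the highest mean over the 8 arrays among those with 1 symbol. Annotation of this kind can be old, and closely related genes can share probe sets.

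Groups and replicate numbers came from the labels. The fit was limma (version 3.58.1 in R 4.3.3) on the log2 values, YAP shRNA minus control shRNA, with empirical Bayes moderation, no block and no filter on dim probe sets. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes were called changed. Single values were compared with two-sided exact permutation tests, for which 4 arrays against 4 allow a smallest p of 0.0286. Gene lists were tested with camera from limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 41 lists. Beside it stand camera with a correlation estimated per list, and fry. Genes named in the report follow a fixed rule, and the closing section says which others were chosen after their values were seen. The rule takes YAP1, WWTR1, TEAD1 to TEAD4 and 7 genes often tied to YAP, namely CCN1, CCN2, ANKRD1, AMOTL2, AXL, BIRC5 and MFAP5. It adds the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and for each list up to 2 risen and 2 fallen members. The design, the named genes' rule, the lists and the alternatives were fixed before the data were examined. A recount without control shRNA replicate 4, a few further lists and the tests by chromosome and by neighbouring genes were added after that.

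The alternatives were quantile normalization, median centring, removal of the dimmest genes by 2 limits on their level, the mean of a gene's probe sets, removal of probe sets prone to cross-hybridisation, every probe set tested, other spread models, array weights, other thresholds, a replicate block and each array left out in turn. In a test on simulated data for this comparison, over 19775 genes, the fit recovered 80% of genes changed by 0.5 log2 and 96% of genes changed by 1 log2, with 11 unchanged genes called and 0 wrong signs. No smaller changes were simulated, while the genes called changed in the data had a median size of 0.313 log2. The simulated noise was independent between genes. Figures were drawn with matplotlib 3.10.9. Probe sets with no or several symbols were left out of the gene-level results and counted apart.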

Results

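Expression was measured in HuCCT1, an established line of bile duct cancer cells, on 8 arrays. In 4 samples the cells carried a control shRNA and in 4 an shRNA against YAP1, which encodes the transcriptional coactivator of the Hippo pathway. Both shRNAs were induced by doxycycline at 100 ng/ml, given for 3 days before seeding. The comparison asks which transcripts differ when YAP1 is knocked down. The series title speaks of overexpression, while the design text and sample labels describe an shRNA, and the YAP1 values below bear on that. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

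YAP1 fell 4.41-fold with the YAP shRNA, from 12.64 ± 0.086 to 10.50 ± 0.070 on the log2 scale (SD, n = 4 and 4). The log2 fold change was -2.14 with a standard error of 0.056 (limma adjusted p = 6.15e-07). The other YAP1 probe sets gave -2.22 and -2.23. All 4 YAP shRNA arrays lay below all 4 control arrays, and the exact permutation p was 0.0286, the smallest that this design allows. WWTR1, which encodes the YAP paralog TAZ, rose by 0.20 (limma adjusted p = 0.0168). Among the TEAD transcription factor genes, TEAD4 fell by 0.13 (limma adjusted p = 0.0348). TEAD1, TEAD2 and TEAD3 had log2 fold changes of -0.15, 0.05 and 0.02 and did not pass the test.

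Several known YAP targets fell. CCN2 and CCN1, secreted matricellular proteins and classical YAP targets, fell 2.41-fold and 2.00-fold, and MFAP5, a microfibril component, fell 2.98-fold. AMOTL2 fell by 0.46 and the receptor tyrosine kinase gene AXL by 0.28. ANKRD1 had a log2 fold change of -0.44 with overlapping groups (limma adjusted p = 0.0848), and BIRC5 one of -0.10 (limma adjusted p = 0.106). Neither passed. In control shRNA replicate 4, ANKRD1 stood at 11.43, within the range of 11.13 to 11.62 on the YAP shRNA arrays. The other control arrays lay above that range, at 11.88 to 12.07. Of 21 measured members of a published YAP and TAZ target list, 10 fell and 1 rose, or 11 and 4 adjusted over the list alone. RBMS3 fell most after CCN2, by 1.12. The member that rose was DOCK5, by 0.18, a gene of chromosome 8, whose genes had a median log2 fold change of 0.11. The list's median was -0.16 (limma camera adjusted p = 2.82e-05; adjusted p = 0.175 with an estimated correlation). Without control shRNA replicate 4, which stood apart from the other control arrays, 12 members fell and 3 rose.

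**Figure D1:**
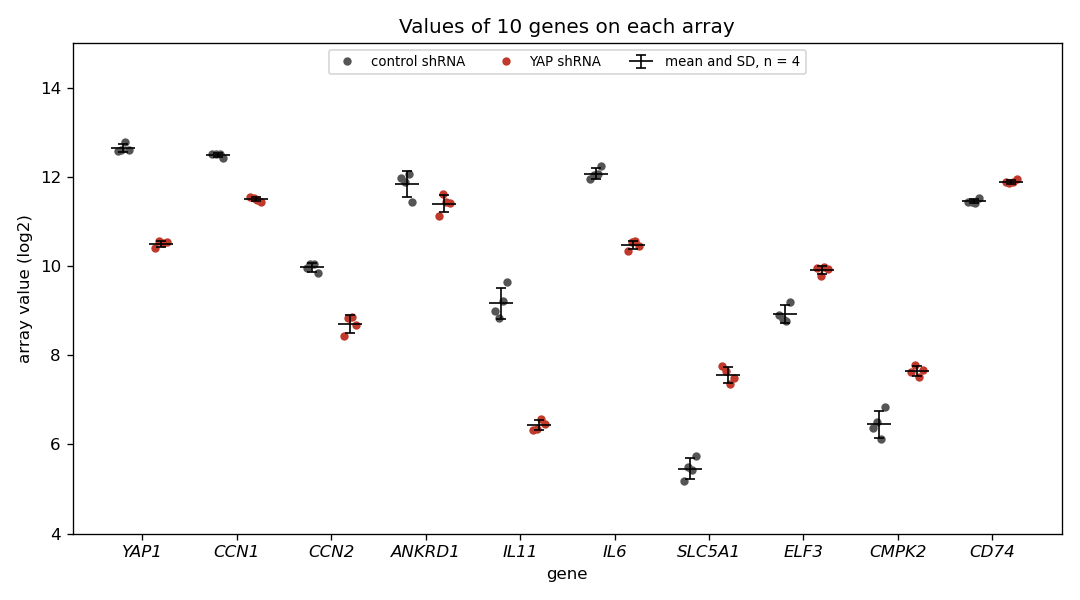
Log2 array values (vertical axis) of 10 genes, with a point per array, 4 control shRNA arrays in grey and 4 YAP shRNA arrays in red, and black bars for the mean and SD. YAP1, CCN1, CCN2, IL11 and IL6 lie lower and SLC5A1, ELF3, CMPK2 and CD74 higher on all 4 YAP shRNA arrays, while the groups of ANKRD1 overlap.

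IL11 and WNT5A were among the steepest falls. IL11, a cytokine of the IL6 family, fell 6.66-fold, from 9.17 ± 0.349 to 6.43 ± 0.111 (SD, n = 4 and 4; limma adjusted p = 2.67e-05), and WNT5A, a non-canonical Wnt ligand, fell 3.59-fold. Falls of between 3.03-fold and 4.50-fold were also seen for CLDN11, SULT1B1, GKN2, VSTM1, SERPINB7, ARID5B, MSRB3, LDB2 and AOX1. Without probe sets prone to cross-hybridisation, LDB2 stood at 0.07 (limma adjusted p = 0.383). SLC5A1, the intestinal sodium and glucose cotransporter, rose most, 4.28-fold, from 5.46 ± 0.232 to 7.56 ± 0.175 (limma adjusted p = 3.49e-05). Rises of between 2.63-fold and 3.35-fold followed for GUCY1A1, TMEM163, C16orf54, GTSF1, SPRR1B, MMP9, S100A14, HSD11B1, DSG3, FGD2 and HPGD. GUCY1A1, TMEM163, C16orf54 and GTSF1 were dim in the control arrays, with means of 4.90, 4.07, 4.53 and 4.26, where the median gene level was 7.44. SPRR1B is a cornified envelope precursor, DSG3 a desmosomal cadherin and MMP9 a gelatinase. FGD2 was not called on its brightest remaining probe set once those prone to cross-hybridisation were left out (limma adjusted p = 0.973). SERPINB7 and DSG3 lie on chromosome 18, whose genes had a median log2 fold change of -0.10, and they moved in opposite directions. C16orf54 lies on chromosome 16, whose median was 0.07.

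Across 19775 genes, 1876 rose and 1418 fell, 3294 in all or 16.7% (limma, adjusted p below 0.05), and 5785 had an unadjusted p under 0.05. Most of these changes were small: 85.0% of changed genes moved by less than 1.5-fold, and 140 moved at least 2-fold, 67 up and 73 down. The 4 arrays of each group did not overlap for 4812 genes, or 24.3%, where chance gives 2.86%. Without control shRNA replicate 4, 3881 genes changed.

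Most epithelial markers rose. Of 25 measured epithelial markers, 15 rose and 0 fell, or 18 and 0 adjusted over the list alone, with a median of 0.29 (limma camera adjusted p = 3.25e-07; adjusted p = 0.0307 with an estimated correlation). It was the 1 list of 41 called with both correlations. ELF3, an epithelial transcription factor, rose by 0.98, and JUP, the desmosomal and junctional plakoglobin, by 0.78. Of 20 mesenchymal markers, ZEB1 and SNAI2, repressors of epithelial genes, fell by 1.09 and 0.65 and 2 others also fell, while MMP9 and S100A4 rose (2 rose and 4 fell adjusted over the list alone). As a set, those markers were not called (limma camera adjusted p = 0.547). SNAI2 is a gene of chromosome 8. Without control shRNA replicate 4, the same number of epithelial markers rose, 15.

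Most interferon-stimulated genes rose, and so did most genes of antigen presentation. Of 36 interferon-stimulated genes, 20 rose and 0 fell, or 24 and 1 adjusted over the list alone, with a median of 0.30 (limma camera adjusted p = 1.93e-08; adjusted p = 0.175 with an estimated correlation). CMPK2, an interferon-induced nucleotide kinase, rose by 1.19. IFI44L rose by 1.15, with groups that overlapped. Of 20 antigen presentation genes, 12 rose and 0 fell, or 12 and 1 adjusted over the list alone, with a median of 0.27 (limma camera adjusted p = 3.79e-05; adjusted p = 0.210 with an estimated correlation). NLRC5, the transactivator of MHC class I genes and a gene of chromosome 16, rose by 0.79, and CD74, the MHC class II invariant chain, by 0.44. Without control shRNA replicate 4, 24 and 12 members of these lists rose. Of 11 leukocyte markers, CD14, LYZ and 1 other rose and PTPRC, which encodes the pan-leukocyte antigen CD45, fell by 0.22. The call on PTPRC, a dim gene with a control mean of 3.96, was lost without control shRNA replicate 4.

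Secretory, hypoxia-linked and pro-apoptotic genes rose in part. Of 19 mucin and secretory genes, 6 rose and 2 fell, or 7 and 2 adjusted over the list alone, with a median of 0.15 (limma camera adjusted p = 0.0170; adjusted p = 0.220 with an estimated correlation). The epithelial mucin genes MUC20 and MUC4 rose by 1.31 and 1.25, and MUC13 and MUC5B fell by 0.28 and 0.26, although MUC5B stood at 0.20 without probe sets prone to cross-hybridisation. The call on this list was lost without control shRNA replicate 3 (limma camera adjusted p = 0.0617). Of 23 hypoxia genes, 9 rose and 3 fell, or 15 and 3 adjusted over the list alone, with a median of 0.18 (limma camera adjusted p = 0.00685; adjusted p = 0.254 with an estimated correlation). NDRG1, a gene of chromosome 8, rose by 0.96 and PFKFB4, a regulator of glycolysis, by 0.50, while LOX and ADM fell by 0.51 and 0.37. Of 18 pro-apoptotic genes, 8 rose and 1 fell, or 10 and 1 adjusted over the list alone, with a median of 0.15 (limma camera adjusted p = 0.0170; adjusted p = 0.254 with an estimated correlation). CASP9, an initiator caspase, rose by 0.42 and BMF by 0.38. PMAIP1, a gene of chromosome 18, fell by 0.29. Without the lower part of genes by level, the hypoxia and pro-apoptotic calls were lost (limma camera adjusted p = 0.0929 and 0.0678). Without control shRNA replicate 4, rises and falls numbered 9 and 1 for the mucins, 13 and 3 for hypoxia, and 10 and 1 for the pro-apoptotic genes.

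A minority of cytoskeletal, cell cycle and chaperone genes fell. Among all genes above the median level, where the median levels of these lists lie, 26.6% changed in either direction. The counts below for S phase and for G2 and M phase fell short of that share, while those for actin and heat shock exceeded it. Of 29 actin cytoskeleton genes, 9 fell and 0 rose, or 10 and 0 adjusted over the list alone, with a median of -0.09 (limma camera adjusted p = 0.000103; adjusted p = 0.175 with an estimated correlation). MYL9, a myosin light chain, fell by 0.95 and TPM2, a tropomyosin, by 0.52. MYL9 was not called without probe sets prone to cross-hybridisation (limma adjusted p = 0.877). Of 54 genes of G2 and M phase, 11 fell and 1 rose, or 13 and 2 adjusted over the list alone, with a median of -0.08 (limma camera adjusted p = 0.000102; adjusted p = 0.456 with an estimated correlation). PIMREG fell by 0.41 and CKAP2 by 0.39, and CBX5, a heterochromatin protein, rose by 0.41. Of 41 S phase genes, 5 fell and 0 rose, also adjusted over the list alone, with a median of -0.04 (limma camera adjusted p = 0.0402; adjusted p = 0.600 with an estimated correlation). TYMS, the thymidylate synthase gene and a gene of chromosome 18, fell by 0.31 and CDC6, a replication licensing factor, by 0.27. The S phase call was lost when any of control shRNA replicates 1 and 3 and YAP shRNA replicates 1 and 3 was left out (limma camera adjusted p = 0.154, 0.100, 0.107 and 0.0515). It was also lost with quantile normalization (0.0793), either limit on dim genes (0.0576 and 0.0820), the mean of a gene's probe sets (0.113) and without probe sets prone to cross-hybridisation (0.278). Of 12 heat shock genes, 4 fell and 0 rose, or 5 and 0 adjusted over the list alone, with a median of -0.07 (limma camera adjusted p = 0.00188; adjusted p = 0.175 with an estimated correlation). HSPH1 fell by 0.38 and DNAJB1 by 0.29. CKAP2 and HSPH1 lie on chromosome 13, whose genes had a median log2 fold change of -0.06, or -0.04 without control shRNA replicate 4. The Hippo pathway list holds YAP1 itself, the targeted gene, which is among its falls and enters its test. Of its 36 members, 12 fell and 5 rose, or 13 and 8 adjusted over the list alone, with a median of -0.06 (limma camera adjusted p = 0.0117; adjusted p = 0.210 with an estimated correlation). AJUBA, a LIM-domain regulator of the pathway, fell by 1.10, and AMOTL1 and VGLL3 rose by 0.34 and 0.23. Without control shRNA replicate 4, rises and falls in these lists numbered 1 and 11 for actin, 1 and 17 for G2 and M phase, 0 and 7 for S phase, 0 and 4 for heat shock and 5 and 14 for the Hippo pathway.

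**Figure D2:**
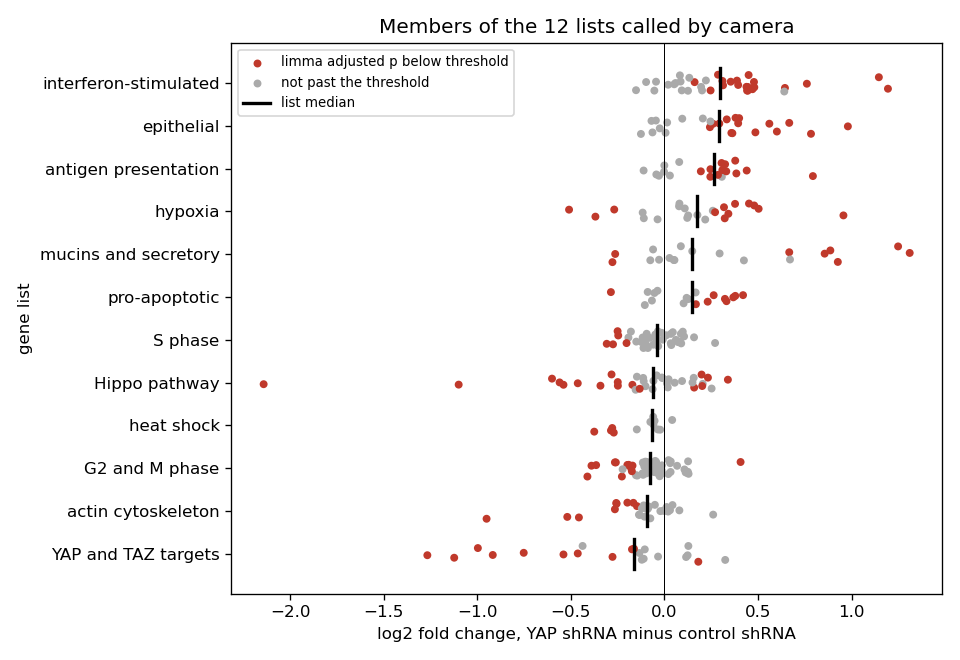
Log2 fold changes (horizontal axis, YAP shRNA minus control shRNA) of the measured members of the 12 gene lists called by camera with the preset correlation, with a point per gene, red where the limma adjusted p passed the threshold, and a black bar at each list's median. Medians range from -0.16 for the YAP and TAZ targets to 0.30 for the interferon-stimulated genes.

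The other 29 lists were not called, and several moved in both directions. Of 29 NF-kB and inflammatory genes, 10 rose and 5 fell (10 and 6 adjusted over the list alone). IL1B and CCL2 rose by 1.04 and 0.93, and IL6 and CXCL2 fell by 1.60 and 0.46. Of 33 angiogenesis factors, 7 rose and 8 fell (7 and 9 adjusted over the list alone), with EFNA1 and NRP2 higher by 0.58 and 0.47, and its steepest falls were those of MFAP5 and CCN2 given above. Of 39 extracellular matrix genes, 7 rose and 7 fell (10 and 9 adjusted over the list alone), with HSPG2 and LAMA4 up by 1.10 and 1.04 and, besides MFAP5, COL12A1 down (fell by 1.24). Of 28 integrin and focal adhesion genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone), with ITGB8 up by 1.23. PARVA fell by 0.29, and 1 of its 7 probe sets went the other way without being called. That probe set gave the 0.07 seen without probe sets prone to cross-hybridisation. Of 22 biliary markers, 8 rose and 1 fell (8 and 1 adjusted over the list alone; limma camera adjusted p = 0.0839, or 0.0122 without control shRNA replicate 4). CFTR, the chloride channel of duct cells, rose by 1.07 and BICC1 fell by 0.29. Of 20 Notch genes, 5 rose and 0 fell, among them DTX4 and NRARP by 0.84 and 0.69 (6 and 0 adjusted over the list alone). Of 21 genes of the TGF-beta response, 3 fell and 0 rose, among them LTBP1 and ID3 by 0.57 and 0.55 (3 and 0 adjusted over the list alone). Of 26 genes of MAPK and EGFR feedback, 5 rose, among them ERBB3 by 0.86 and SPRY1 by 0.68, and 3 fell, among them DUSP1 by 0.64 (7 and 3 adjusted over the list alone).

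Metabolic, housekeeping and cell type lists were among those not called. Rises and falls numbered 4 and 4 of 26 drug transport genes, 5 and 4 of 21 NRF2 targets, 5 and 1 of 14 fatty acid synthesis genes and 2 and 1 of 19 cholesterol synthesis genes. Adjusted over the list alone, they numbered 6 and 5, 6 and 4, 6 and 1, and 2 and 1. ABCC3, a drug exporter, rose by 0.94, and 1 of its 5 probe sets went the other way without being called. That probe set gave the -0.04 seen without probe sets prone to cross-hybridisation. SREBF1, the lipogenic transcription factor, rose by 0.46, and SQLE, a gene of chromosome 8, by 0.21. They numbered 4 and 0 of 21 glycolysis genes, 1 and 1 of 33 oxidative phosphorylation genes, 5 and 3 of 23 autophagy and lysosome genes, 0 and 3 of 23 genes of the unfolded protein response and 3 and 4 of 25 p53 targets. Adjusted over the list alone, these were 4 and 0, 1 and 1, 8 and 3, 0 and 2, and 4 and 5. CYC1 of the oxidative phosphorylation list and CTSB of the lysosome list, both genes of chromosome 8, rose by 0.22 and 0.42, and NPC1, of chromosome 18, fell by 0.30. The 26 MYC-linked ribosome biogenesis genes gave 0 and 1, also adjusted over the list alone (limma camera adjusted p = 0.126, or 0.00869 without control shRNA replicate 4). None of 37 ribosomal protein genes changed by limma, and RPL3, with the smallest adjusted p, stood at 0.06 (0.292). Rises and falls were 4 and 1 of 12 keratins, 1 and 0 of 16 Wnt targets, 1 and 0 of 15 core histones, 1 and 0 of 12 genes of small RNA machinery and 1 and 1 of 9 survival genes. Adjusted over the list alone, they were 4 and 1, 1 and 0, 1 and 0, 0 and 0, and 2 and 3. Among markers of other cell types, 1 rose and 1 fell of 21 for hepatocytes, 1 and 2 of 14 for fibroblasts, 3 and 1 of 11 for leukocytes and 0 and 0 of 12 for endothelium, with the same counts adjusted over the list alone. PECAM1, the endothelial marker with the smallest adjusted p, stood at 0.25 (limma adjusted p = 0.162). In 11 of the 29 lists the median, the mean and the direction of the test differed in sign, among them the angiogenesis, matrix, integrin and mesenchymal lists.

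RNA quality differed little between the groups. The 3' minus 5' log2 difference of the GAPDH control probe sets was 0.198 ± 0.0116 in control arrays and 0.178 ± 0.0114 in YAP shRNA arrays (SD, n = 4 and 4; two-sided exact permutation p = 0.0857). For ACTB it was 0.990 ± 0.0879 and 1.02 ± 0.0920 (exact permutation p = 0.686). The first principal component held 48.0% of the variance and separated the groups, and the second held 20.7% and separated control shRNA replicate 4, at -23.0, from the other arrays, at -6.39 to 12.3.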

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

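Of the tests in this part, the check of 3' to 5' differences and the comparison of intron-retaining transcripts with the YAP shRNA arrays were chosen only after the result was seen, and the list of intron-retaining transcripts was written after the most deviating genes of control shRNA replicate 4, which it leaves out, had been seen, although its member GOLGA8B is a close copy of GOLGA8A. In 216 groups of 4 values, made of 101 genes the text names and 7 array measures, 18 had 1 array far from the other 3, where chance gives about 10.8, and 7 of the 18 lay in control shRNA replicate 4.

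In control shRNA replicate 4, CCN1 was lower at 12.43 (12.52 in the other 3 control arrays), CCL2 lower at 7.84 (8.38 to 8.48) and COL12A1 lower at 10.08 (10.48 to 10.52). MFAP5 was higher at 10.61 (10.17 to 10.20), LOX at 10.66 (10.44 to 10.47) and SQLE at 11.69 (11.54 to 11.55). Its mean correlation with its group across genes was 0.9967, under 0.9978 to 0.9980 for the others. Single arrays also stood apart for CLDN11 (7.76) and TYMS (11.63) in control shRNA replicate 1 and for YAP1 (12.77) in control shRNA replicate 3. The same held for EFNA1 (7.77) in YAP shRNA replicate 1, BICC1 (10.77) and MYL9 (6.43) in replicate 2, ADM (9.31) in replicate 3, and ABCC3 (8.54) and LAMA4 (9.54) in replicate 4. The 3' minus 5' difference of GAPDH was low at 0.181 in control shRNA replicate 3, and that of ACTB high at 1.16 in YAP shRNA replicate 1. Among 13522 probe sets with no or several gene symbols, which no comparison used, 305 passed the limma threshold, 170 higher and 135 lower.

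Relative to the mean of the other 3 control arrays, control shRNA replicate 4 was lowest in ANKRD36B, PABPC1L, GOLGA8A, RSRP1 and CCNL2, by -1.85 to -1.39, and among its highest were TFF1, AKR1C3, SLPI, PI3 and SPRR1B, by 1.15 to 0.69 (genes chosen after their values were seen). Noise of dim probe sets is argued against, since its spread was 2.05 times that of the other control arrays in the upper part of expression. Mixing with YAP shRNA cells could account for a small part. Its deviation had a slope of 0.135 on the YAP shRNA fold change, against 0.0510 or less in the others. That explained 5.43% of its variance over changed genes. Over 72 genes at least 2-fold higher when this array was left out, its median deviation was 0.275, which would need 15.8% of YAP shRNA cells. Over 73 genes at least 2-fold lower it was -0.0521 (95% bootstrap bounds over genes of -0.170 and 0.0214), where such mixing predicts -0.135. YAP1 deviated by -0.0521, where mixing predicts -0.188. IL11 and MFAP5 deviated the other way, by 0.62 and 0.42. A list of 37 other intron-retaining transcripts, such as CLK1 and NKTR (also named after their values were seen), had a median deviation of -0.228. That was below the lowest of 10000 random lists at -0.0725. Random lists treat genes as independent and do not measure the spread between arrays. Control shRNA replicate 3, at 0.117, passed the bound of 0.1 set beforehand for the other control arrays. A lower share of such RNA therefore stays open. Mixing is argued against for these transcripts by the list's median of 0.000715 in the YAP shRNA arrays. RNA quality cannot be told apart from a culture difference, since its ACTB 3' minus 5' difference was the lowest of all arrays at 0.883 and its GAPDH value of 0.2048 barely the highest; no biological explanation was tested.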

How the results depend on the processing

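YAP1 kept its direction and its call in every alternative run, with log2 fold changes of -2.16 to -2.10 when 1 array was left out. Leaving out 1 array gave 2381 to 3881 genes changed, 133 to 145 changed at least 2-fold, 10 to 14 lists called, adjusted p of 3.87e-06 to 0.00019 for the YAP and TAZ target list, and 3' to 5' differences between groups of -0.0255 to -0.0163 for GAPDH and -0.0129 to 0.0691 for ACTB. GAPDH passed the exact test without control shRNA replicate 3 (p = 0.0286), and ACTB turned sign without control shRNA replicate 4 (-0.00264) and without YAP shRNA replicate 1 (-0.0129). The labels do not say that the numbers pair the samples, and the values gave no sign of it. Deviations of same-numbered arrays correlated at -0.170, -0.0588, 0.00203 and -0.206 across genes, and no array correlated best with its own number. With the replicate block 2106 genes changed in place of 3294. Testing every probe set gave 5580, and an adjusted p below 0.01 gave 1785, fewer by construction. Genes changed at least 2-fold numbered 80 without the lower part of genes by level, where fewer genes were tested, and 88 with the mean of a gene's probe sets. With an estimated correlation the YAP and TAZ target list had an adjusted p of 0.175, over a range of 3.39e-06 to 0.175 in all alternatives, and 1 list was called in place of 12; fry, which does not compare a list with other genes, called 21, of which 11 were shared, without the genes of G2 and M phase (adjusted p = 0.0585, in a range of 1.02e-07 to 0.456). Of 24 calls on single lists lost under the alternatives, besides the YAP and TAZ target list, 10 were lost with an estimated correlation. S phase lost its call with quantile normalization (0.0793), without the dimmest genes by either limit (0.0576 and 0.0820), with the mean of a gene's probe sets (0.113), without probe sets prone to cross-hybridisation (0.278), with the replicate block (0.0503) and without any of 4 arrays, in a range of 0.00458 to 0.600. Without the lower part of genes by level, the hypoxia genes (0.0929, in a range of 0.000564 to 0.254) and the pro-apoptotic genes (0.0678, in a range of 0.000908 to 0.254) lost theirs, and without control shRNA replicate 3 the mucins did (0.0617, in a range of 0.000770 to 0.220). Without probe sets prone to cross-hybridisation the direction turned for ABCC3 (-0.0427), AKR1C1 (0.000862), AKR1C2 (0.157), LDB2 (0.0722), MUC5B (0.199), PARVA (0.0684) and TEAD2 (-0.286). That setting left out probe sets by the ending of their IDs and took the brightest remaining one of each gene. TEAD3 turned without control shRNA replicate 2 (-0.0116) and 3 (-0.00216), in a range up to 0.0520. Of the 132 called genes besides YAP1 that the naming rule takes, 94 kept their call in all settings and 36 lost it with the same direction in at least 1. The cause was not tested. Floors before taking logs were not run, since the values are already log2. Without detection calls, signal over background limits the dim genes: among genes parted into 4 equal classes by level, 117 changed in the dimmest class and 1523 in the one below the brightest.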

Other observations

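Of the tests in this part, the shuffles of the chromosome medians, the medians over 3 equal parts of chromosome 8, the gene density trend and the leukocyte markers were chosen only after the result was seen, and the lists of STAT3 targets, epidermal genes and metalloproteinases were added after the first results but before their own. The genes PIM1, MMP7, SPRR1A, DSC3 and IFNK, and those that bound the run on chromosome 8, fall outside the naming rule and were chosen after their values were seen.

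IL6 and IL11 fell, yet targets of the STAT3 signal that these cytokines drive did not fall as a set. Of 25 such targets, 7 rose, PIM1 by 0.68, and 0 fell, or 8 and 1 adjusted over the list alone, with a median of 0.10. A lower set had been the hypothesis, and the set lay higher (limma camera p = 0.00300; p = 0.172 with an estimated correlation). MMP9 rose and so did MMP7, by 1.25, but of 20 other metalloproteinases 2 rose and 1 fell, or 3 and 1 adjusted over the list alone. Those did not pass as a set (limma camera adjusted p = 0.273, over 3 lists). Most of these 20 were dim, in the lower part of expression, which limits what the test of the set could show. SPRR1A rose by 1.16 beside SPRR1B. Of 37 epidermal differentiation genes, SPRR1A among them, 8 rose and 1 fell, DSC3, by 1.30, with the same counts adjusted over the list alone. KRT13 and OVOL1, which are also in the keratin and epithelial lists, were among the rises. The 37 fell short of a shift as a set (limma camera p = 0.0604, or p = 0.344 with an estimated correlation). Most of the 37 lay in the lower part of expression, so a rise confined to brighter members could be missed.

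Genes of chromosome 8, by gene order in GRCh38.p14, were higher as a group: among its 368 genes in the upper part of expression the median log2 fold change was 0.11, 130 rose and 19 fell, and 40.5% changed against 26.6% of all such genes; the shuffled p was 1e-04, the smallest 10000 shuffles can give (0.00046 adjusted over 23 chromosomes). The shuffles treat genes as independent, so this p does not measure the spread between arrays. The median was 0.108 to 0.116 in each of the 4 YAP shRNA arrays against the control mean. It was -0.0333 to 0.0696 in each control array against the other 3, highest in control shRNA replicate 4. Chromosome 8 lay 3.57 residual SDs off the trend of the other chromosomes with gene density. That goes against such a trend only weakly, since chromosome 8 was looked at for having the largest median of all. Control shRNA replicate 4 is argued against as the source, since the median was 0.124 without it. A copy number difference between the cultures could give such a shift, although 3 copies in place of 2 in every cell would give 0.58 for a transcript that follows its copies. The lowest median among 3 equal parts of the chromosome was 0.0628, while the largest run of 50 neighbouring genes, PHF20L1 to C8orf82, reached 0.213 (0.149 at most in 100 shuffles), between the bounds of 0.2 and 0.3 set beforehand; an effect of the knockdown stays open and untested.

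Most interferon-stimulated and antigen presentation genes rose. Control shRNA replicate 4 is argued against as the source, since the interferon median was 0.305 without it, and so is noise of dim probe sets, since the 45 members in the upper part of expression had a median of 0.286. For leukocytes mixed into the YAP shRNA cultures, the values such cells would need were not seen. The median of 11 markers was 0.0750 against 0.298 for the interferon list, and 7 of the 11 did not pass. PTPRC fell by 0.22, a call that was lost without control shRNA replicate 4. The samples are of an established cancer cell line, so such cells would have to come from outside it. The values could not exclude them, since the markers are dim, with control means of 6.33 at most. LYZ, which is also in the mucin and secretory list, rose by 0.86. The upper quartile of the markers was 0.232 with 95% bootstrap bounds of 0.0691 and 0.659. Those bounds resample the markers and do not measure the spread between arrays. A response to the YAP shRNA's own sequence could not be excluded. One to shRNAs or doxycycline in general would also reach the control arrays, whose shRNA was induced in the same way. Of 18 interferon ligand genes 0 rose by limma and IFNK fell by 0.73 (limma adjusted p = 0.0123), the 1 with an unadjusted p under 0.05. Most of the 18 lie near the floor, however, and the design has 1 YAP shRNA. An effect of the knockdown stays open for the same reason.

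Among the splits of the 8 arrays, only the real one reached its counts of genes, while another reached its count of lists. The real grouping gave 3294 genes changed and 140 at least 2-fold. The highest of the other splits gave 0 and 0, so 1 of 35 splits reached each count. Splits that mix the groups carry the group difference in their spread, which leaves few calls. The counts therefore cannot exclude a chance difference between the cultures. For lists, 2 of 35 splits called 12, the real one and one that exchanged control shRNA replicate 4 with YAP shRNA replicate 2, which keeps most of the real contrast. In that split the YAP and TAZ target list had a camera p of 6.68e-07, against 2.06e-06 in the real one, so 2 of 35 splits gave a p as small. The labels give 1 YAP shRNA, so off-target action of the single YAP shRNA was not tested.

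In the shuffles of genes between chromosomes, 11 of 23 chromosomes passed after adjustment, 4 above the median of all genes in the upper part of expression and 7 below it. Beside chromosome 8, the medians farthest out were -0.10 for chromosome 18, with 43 falls and 7 rises, 0.07 for chromosome 16, with 102 rises and 24 falls, and -0.06 for chromosome 13, with 38 falls and 16 rises (-0.04 without control shRNA replicate 4). The other 7 that passed had medians of -0.03 to 0.03. Since the shuffles treat genes as independent, a pass does not measure the spread between arrays.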
